A study of Mus musculus with 8 samples.

How the data were processed

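The data were RNA-seq libraries of MLO-Y4 cells, 4 controls and 4 treated with an antisense oligonucleotide (ASO) against H19, all exposed to shear stress of 2 Pa for 4 cycles. Group and replicate number were taken from the sample titles. Per the labels, RNA was extracted with Trizol. The library kit and its strandedness are not clear from the labels, so reads of a gene and an antisense partner cannot be told apart. The submitters' processing notes name HISAT, Bowtie2 and the builds GRCm38.p6 and mm10, without roles or versions. The counting tool and the annotation are not given in the sources used here.

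The authors deposited 1 table of 16369 genes with, per library, estimated counts, FPKM and TPM, and the mean of each group, per the file headers. The deposited estimated counts were not whole in 6.01% to 6.60% of the genes of a library, tested with a tolerance of 0, and were rounded before testing. Counts that are not whole were taken to mark reads assigned in parts to several genes, which was not tested, as the counting tool is not given. They occurred in 1300 of the tested genes, 151 of them past the threshold. FPKM values, per the file headers, are scaled by the authors to gene length and depth, and the authors' TPM columns sum to the same total in each library, within rounding. The deposited mean columns equalled the mean of the 4 libraries and were not used further. Of the gene identifiers, 16321 (99.7%) matched the reference annotation of GRCm38.p6, which gave the coordinates.

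Libraries held 19501980 to 19914213 estimated reads, so that 1 CPM stood for about 19.5 reads, and a gene with 0 reads could lie at up to 0.15 CPM (3 reads), a limit for counting error alone. The replicates of a group differed by more than sampling noise, with chi-square per degree of freedom from 4.71 to 18.3, and no library was a repeat of another.

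Genes were filtered with filterByExpr (12227 kept), scaled by TMM and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3) with group as the single term and Benjamini-Hochberg adjustment at 0.05. Log2 fold changes are ASO over control, with standard errors derived from the test's F statistic. CPM are per library after TMM. A set of 34 gene lists with 889 members, 811 of them matched to a row, was fixed before the data were examined. Lists with at least 5 tested members (29) were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), again with an estimated correlation, and with fry. Member calls were adjusted over all genes and over the list alone. Older symbols were matched through synonyms only where the symbol was not the current name of another gene. This last condition was added after false matches had been seen.

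The named genes followed a rule set at the same time: H19 and Igf2; the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, with a mean of at least 1 CPM in the higher group and no predicted, clone or pseudogene name; up to 4 members with the smallest p of each list that passed camera or held at least 3 calls; and Tnfsf11, Tnfrsf11b, Sost, Dkk1, Dmp1, Ptgs2, Gja1, Piezo1, Ptk2, Runx2, Hmga2 and Igf1r. H19, Dkk1 and the mitochondrially encoded genes are not analysed here, and 1 gene that the rule names is not reported here.

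The procedure was tested on simulated data made from the means, depths and dispersions of these libraries, in 10 simulations of 12227 genes with 200 changed. For the comparison of ASO with control, edgeR recovered 40.6% of genes changed 1.25-fold, 81.6% at 1.5-fold, 93.8% at 2-fold and 99.2% at 4-fold. False calls made up 7.24% of its calls over the 10 simulations (4.27% to 11.6% in single ones), above the nominal 5%. They were 10.3% for DESeq2, 6.60% for limma-voom and 7.56% for limma-trend. The share among the real calls may also lie above 5%, but the simulations do not measure it. They changed 200 genes, while 1790 passed in the real data. The 10 simulations replaced a single one after its share of false calls had been seen to be above 5%, and include it. Camera found a simulated list of 40 genes shifted 1.2-fold and called 0 of 20 unchanged lists. These simulated genes varied independently, unlike real genes of a pathway.

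Alternatives were DESeq2 1.42.0 and its size factors, upper-quartile and library-size scaling, no filter and a stricter one (at least 5 CPM in 4 libraries), limma-voom, robust edgeR, a replicate block, each library left out, limma-trend on log2(FPKM + 1) and log2(TPM + 1) with a mean of at least 1, a pseudocount of 0.1 or no filter, and an adjusted p under 0.01. After samples 1 and 2 had been seen to separate from samples 3 and 4, this division was added as a term, and each part was tested alone. A further 6 gene lists were also chosen after the data were seen: clock genes driven by E-boxes or D-boxes, clock genes driven by ROR elements, antigen processing and class I genes, small leucine-rich proteoglycan genes, basement membrane genes and mineralisation genes.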

Results

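RNA-seq was done on 8 libraries from MLO-Y4, an established mouse cell line with osteocyte properties. All 8 samples came from cells in fluid chamber slides exposed to fluid shear stress of 2 Pa for 4 cycles. In 4 of them an antisense oligonucleotide (ASO) was used to silence the long non-coding RNA H19, and the other 4 were controls. The deposited columns and sample descriptions call the controls NC, which is not spelled out. What the control cells received is not stated, so a response to an oligonucleotide as such is not separated from that to less H19. No library came from cells without shear stress, so the single comparison, H19 ASO against control, describes the ASO under flow and not the response to flow. The series was designed around H19 in osteocyte mechanotransduction. The libraries held between 19501980 and 19914213 estimated reads. Nothing in the labels says whether the 4 libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

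With the ASO, 1790 of 12227 tested genes differed from control, 869 higher and 921 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, n = 4 per group). Most changes were small: the median absolute log2 fold change of these genes was 0.38, and 224 of them changed at least 2-fold, 157 upwards and 67 downwards. The number with at least 2-fold change was 35 with a stricter filter and 20 to 135 on log2 FPKM or TPM scales. In 1507 of the 1790 genes the 4 ASO libraries all lay on one side of the 4 control libraries. Of all tested genes, 19.1% were separated in this way, against 2.86% by chance. The first principal component, with 46.0% of the variance, separated the groups, with ASO libraries from 12.5 to 21.9 and control libraries from -23.4 to -10.8. The second, with 17.1%, separated samples 1 and 2 from samples 3 and 4 in both groups. This division is not in the labels, and each group holds samples of both parts. Between samples 3 and 4 and samples 1 and 2, with group as a term, 1443 genes differed, 642 higher and 801 lower. With the division as a term, 3136 genes differed between ASO and control. Within samples 1 and 2 alone 1022 genes differed between ASO and control, within samples 3 and 4 alone 2132 did, and 702 were called in both with the same sign, against 89.1 for independent lists. A further 1 gene was called in both with opposite signs. The count was 1105 without control replicate 2, 1191 without ASO replicate 3 and 1129 without ASO replicate 4.

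**Figure D1:**
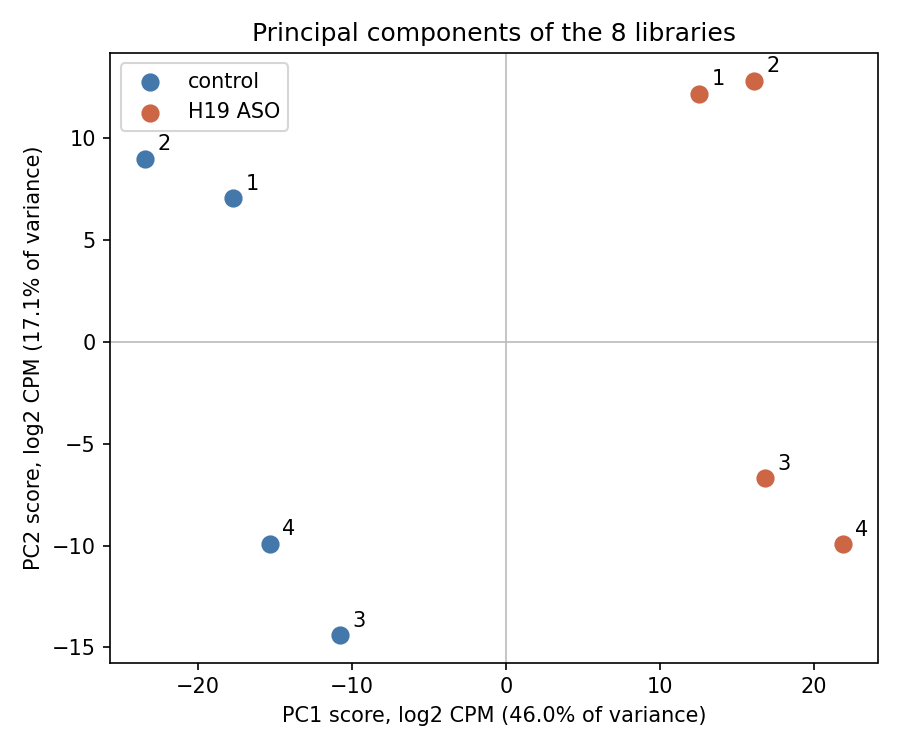
Scores of the 8 libraries on the first and second principal components of log2 CPM, with replicate numbers beside the points and colours for control and H19 ASO. The first component (46.0% of variance) separates the groups and the second (17.1%) separates samples 1 and 2 from samples 3 and 4.

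H19 is not analysed here, so the labels could not be checked by the level of the silenced transcript. Igf2, the growth factor gene that neighbours H19 in the imprinted cluster, had between 0 and 8 reads per library and was below the filter. Of 8 tested members of the imprinted gene network, 0 were higher and 2 were lower, and the same 2 were lower when adjusted over the list alone (camera adjusted p = 0.27). They were the zinc finger gene Plagl1 (log2 fold change -0.38 ± 0.06 SE, adjusted p = 7.8e-04) and the proteoglycan gene Dcn (-0.35 ± 0.11, adjusted p = 0.041), both named after their values were seen. Among 27 targets of the let-7 microRNA, which H19 is known to bind, 1 was higher and 3 were lower, with 4 higher and 3 lower adjusted over the list alone and 5 and 3 with the sample division as a term (camera adjusted p = 0.71). Cdk6, a cell cycle kinase gene, had a log2 fold change of 0.30 ± 0.08 (adjusted p = 0.023) and Thbs1, which encodes thrombospondin, -0.39 ± 0.08 (adjusted p = 0.0050). The let-7 targets Hmga2 (0.00075 ± 0.12, adjusted p = 1.00) and Igf1r (0.15 ± 0.06, adjusted p = 0.12) did not pass. The call of Cdk6 ended without control replicate 2 or 4 or ASO replicate 4 (adjusted p up to 0.078). Those of Cdc25a (adjusted p up to 0.10) and Tgfbr1 (up to 0.12), the other lower members, each ended in at least 6 of the 8 fits that left out 1 library, and both held without ASO replicate 1.

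Of the 10 largest rises, all but that of Il18r1 were in genes with a mean below 4 CPM. Il18r1, a subunit of the interleukin-18 receptor (gene 16182, chromosome 1, 40465552 to 40500854, GRCm38.p6), rose from 1.34 ± 0.64 CPM to 15.6 ± 1.04 CPM (SD, n = 4), a log2 fold change of 3.53 ± 0.20 (SE, adjusted p = 1.3e-06). Gpr84, a receptor for medium-chain fatty acids (gene 80910, chromosome 15, 103308233 to 103310670), rose from 0.55 ± 0.10 CPM to 4.58 ± 0.69 CPM (log2 fold change 3.04 ± 0.20, adjusted p = 2.5e-06). The interleukin-36 receptor gene Il1rl2 rose by 2.65 ± 0.37. Il4i1, an amino acid oxidase gene, had the highest log2 fold change at 3.90 ± 0.54, from 9 control reads in all against 144 in ASO libraries. Control replicate 3 held 8 of the 9 reads, and without it the log2 fold change was 6.27. Some of its counts were not whole, which leaves its value uncertain. Fam71a, Fam71d, Cyp2c55, Chrna10, Hsf5 and Ddn completed the 10 largest rises, with log2 fold changes between 2.68 and 3.26 and at most 0.38 CPM in controls. The largest falls were smaller. Crct1 (-1.92 ± 0.31), the small proteoglycan gene Aspn (-1.89 ± 0.32) and Agt, which encodes angiotensinogen (-1.70 ± 0.23, 12.2 ± 4.09 CPM to 3.74 ± 0.92 CPM), led them. Cyp2f2, Cnnm1, Olfml2a, Ces1a, Eln and Dmp1 followed, between -1.65 and -1.46.

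Part of the collagen and matrix genes fell. The type I collagen genes of bone did not pass: Col1a1 (log2 fold change 0.12 ± 0.11, adjusted p = 0.51) and Col1a2 (-0.12 ± 0.10, adjusted p = 0.47). Of 33 tested collagen and matrix genes, 12 were lower and 0 higher (15 lower adjusted over the list alone, 22 with the sample division as a term), with a median log2 fold change of -0.22 (-0.25 in samples 1 and 2, -0.19 in samples 3 and 4). Eln, the elastin gene (gene 13717, chromosome 5, 134702595 to 134747368), fell from 17.8 ± 4.91 CPM to 6.46 ± 1.92 CPM (log2 fold change -1.46 ± 0.21, adjusted p = 8.5e-04). The basement membrane collagen genes Col4a1 (-0.54 ± 0.09) and Col4a2 (-0.41 ± 0.07) and the crosslinking enzyme gene Loxl2 (-0.38 ± 0.07, with counts that were not whole) also fell. The list passed camera with its preset correlation (adjusted p = 4.3e-06), but with an estimated correlation the adjusted p = 0.71. Genes for perilacunar remodelling and matrix proteases were lower in 8 of 24 cases and higher in 0, with the same numbers adjusted over the list alone and a median of -0.20 (-0.19 and -0.12 in the same order of samples). Mmp13, the collagenase gene (gene 17386, chromosome 9, 7272514 to 7283333), fell from 161 ± 12.4 CPM to 79.1 ± 13.6 CPM (log2 fold change -1.02 ± 0.10, adjusted p = 8.1e-05). The aggrecanase gene Adamts4 fell by 1.12 on the log2 scale, from 40.9 ± 10.2 CPM to 18.8 ± 1.39 CPM, and Plat and Mmp2 fell by 0.36 and 0.31. Camera gave an adjusted p = 0.0042 for this list, and an adjusted p = 0.71 with an estimated correlation.

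Markers of bone cells moved both ways. Of 14 osteocyte genes 3 were higher and 4 lower (3 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.48). Dmp1, a mineralisation gene of osteocytes (gene 13406, chromosome 5, 104197575 to 104214102), fell from 1.82 ± 0.59 CPM to 0.66 ± 0.33 CPM (log2 fold change -1.46 ± 0.34, adjusted p = 0.012). Tnfrsf11b, which encodes the decoy receptor osteoprotegerin (gene 18383, chromosome 15, 54250619 to 54278484), fell from 11.6 ± 1.09 CPM to 6.61 ± 2.09 CPM (log2 fold change -0.81 ± 0.17, adjusted p = 0.0075). Fbln7 (-0.46 ± 0.09) and Dstn (-0.25 ± 0.06) were lower too. Tnfsf11, which encodes RANKL, the ligand that osteoprotegerin binds, was not called (log2 fold change 0.33 ± 0.17, adjusted p = 0.20), although it passed in samples 3 and 4 alone (0.61, adjusted p = 0.017) and not in samples 1 and 2 (0.06, adjusted p = 0.81). That pass rested on ASO replicate 4, at 17.0 CPM, as ASO replicate 3 was at 9.16 CPM and the controls at 9.17 and 7.98 CPM. Sost, which encodes sclerostin, had between 0 and 2 reads per library, and Dkk1 is not analysed here. Of 11 ligands that regulate osteoclasts, 1 was higher and 2 were lower (1 and 4 adjusted over the list alone, 2 and 5 with the sample division as a term, camera adjusted p = 0.28), with Il6 at 0.94 ± 0.26 and Ccl7 at -0.42 ± 0.10. Among 11 osteoblast genes 2 were higher and 2 lower, and the same numbers held adjusted over the list alone (camera adjusted p = 0.77, with a median of 0.08 and a mean of -0.03 that differ in sign). Alpl, the alkaline phosphatase gene, rose by 0.37 ± 0.07 and Sp7 by 0.43 ± 0.12, whereas the osteocalcin genes Bglap2 (-0.72 ± 0.13) and Bglap (-0.60 ± 0.15) fell, both near-identical copies with counts that were not whole. Runx2 did not pass (0.08 ± 0.08, adjusted p = 0.50). The call of Bglap ended without control replicate 2 (adjusted p = 0.052), and those of Sp7 (up to 0.063) and Il6 (up to 0.088) each ended in 5 of the 8 fits that left out 1 library. Sp7 held without control replicate 2, ASO replicate 3 or ASO replicate 4, and Il6 without control replicate 1, ASO replicate 1 or ASO replicate 3.

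Genes known to respond to shear stress also divided. Of 30 tested, 3 were higher and 7 lower (5 and 9 adjusted over the list alone, camera adjusted p = 0.48). Dusp6, a phosphatase gene that limits ERK signalling (gene 67603, chromosome 10, 99263231 to 99267489), fell from 130 ± 15.4 CPM to 73.1 ± 2.11 CPM (log2 fold change -0.83 ± 0.08, adjusted p = 5.2e-05). Tnfaip3, an inhibitor of NF-kappaB, fell by 0.54 on the log2 scale and the chemokine gene Ccl7 by 0.42, whereas the cytokine gene Lif rose by 0.54 ± 0.11. Ptgs2, the cyclooxygenase gene induced by flow, differed by less than the spread between replicates, at 485 ± 50.1 CPM and 454 ± 35.8 CPM (log2 fold change -0.09 ± 0.08, adjusted p = 0.46), although it passed in samples 3 and 4 alone (-0.30, adjusted p = 0.0074), with the opposite sign in samples 1 and 2 (0.12, adjusted p = 0.34). Whether Ptgs2 or Tnfsf11 differed between the parts of the samples was not tested. The connexin gene Gja1 (-0.0064 ± 0.06, adjusted p = 0.96), the channel gene Piezo1 (-0.18 ± 0.07, adjusted p = 0.088) and the focal adhesion kinase gene Ptk2 (0.12 ± 0.06, adjusted p = 0.19) did not pass either, but Piezo1 did with the sample division as a term (adjusted p = 0.033).

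Of 20 contractile and serum response factor targets 5 were lower and 1 higher, with the same numbers adjusted over the list alone and a median of -0.15 (-0.13 and -0.18 in samples 1 and 2 and samples 3 and 4). Tagln, an actin-binding protein gene of smooth muscle, fell from 31.9 ± 5.98 CPM to 18.1 ± 4.23 CPM (log2 fold change -0.82 ± 0.16, adjusted p = 0.0044), Actg2 by 0.55 and Thbs1 by 0.39, and Tagln2 rose by 0.26 ± 0.06. Camera gave an adjusted p = 0.0027 and, with an estimated correlation, an adjusted p = 0.73. In samples 1 and 2 alone the adjusted p = 0.051. Of 28 integrin and focal adhesion genes 4 were lower and 0 higher (9 lower and 2 higher adjusted over the list alone, 10 and 2 with the sample division as a term, camera adjusted p = 0.15). Vcl, the vinculin gene, fell from 839 ± 77.5 CPM to 535 ± 97.0 CPM (log2 fold change -0.65 ± 0.11, adjusted p = 0.0022), and Fermt2, Tns1 and Zyx by 0.28, 0.47 and 0.25. Targets of the mechanosensitive coactivators YAP and TAZ were lower in 4 of 24 cases and higher in 0, also adjusted over the list alone (6 lower and 2 higher with the sample division as a term, camera adjusted p = 0.48, and 0.044 in samples 3 and 4 alone). With an estimated correlation the adjusted p = 0.80. Crim1 (-0.49 ± 0.08), Dock5 (-0.39 ± 0.07), Ccn2 (-0.53 ± 0.13) and F3 (-0.61 ± 0.15) were the 4. Of 20 genes for mechanosensitive channels, purinergic receptors and the primary cilium 1 was lower, Pkd1 (-0.35 ± 0.10, adjusted p = 0.039, named after its value was seen), and 0 passed adjusted over the list alone (4 lower and 1 higher with the sample division as a term, camera adjusted p = 0.48). Without control replicate 4 the calls of Ccn2 and F3 ended (adjusted p = 0.052 and 0.056), and those of Tns1 (up to 0.094) and Zyx (up to 0.13) ended in 6 and 5 of the 8 fits that left out 1 library. Both held without ASO replicate 1, Tns1 also without control replicate 3, and Zyx also without control replicate 1 or ASO replicate 3.

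Of 16 Wnt targets and antagonists 1 was higher and 4 lower (2 and 6 adjusted over the list alone, also with the sample division as a term, camera adjusted p = 0.25, with a median of -0.09 and a mean of 0.04 that differ in sign). Sfrp4, a secreted Wnt antagonist gene, fell from 427 ± 13.3 CPM to 261 ± 30.4 CPM (log2 fold change -0.71 ± 0.08, adjusted p = 9.5e-05). Rnf43 rose by 2.81 ± 0.50 from 0.10 ± 0.09 CPM, Ctnnb1, the beta-catenin gene, fell by 0.21 and Fzd1 by 0.33. Among 25 genes that respond to TGF-beta or BMP 3 were higher and 4 lower (3 and 6 adjusted over the list alone, 4 and 8 with the sample division as a term, camera adjusted p = 0.61). Inhba, an activin subunit gene, fell from 796 ± 28.2 CPM to 512 ± 61.3 CPM (log2 fold change -0.64 ± 0.08, adjusted p = 2.9e-04) and Tgfb3 by 0.49, whereas the latent TGF-beta binding protein genes Ltbp2 (0.56 ± 0.08) and Ltbp1 (0.40 ± 0.07) rose. The call of Ctnnb1 ended without control replicate 2 (adjusted p = 0.053) and that of Fzd1 (up to 0.074) held only without control replicate 3, control replicate 4 or ASO replicate 1.

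Genes of G2 and mitosis rose together. Of 52 tested, 40 were higher and 0 lower (47 higher adjusted over the list alone), with a median log2 fold change of 0.39 (0.33 in samples 1 and 2, 0.45 in samples 3 and 4), and all 52 had a positive log2 fold change. Plk1, a mitotic kinase gene (gene 18817, chromosome 7, 122159435 to 122169884), rose from 48.5 ± 2.32 CPM to 81.1 ± 9.78 CPM (log2 fold change 0.74 ± 0.08, adjusted p = 1.1e-04). Cenpf, a kinetochore gene, rose by 0.60 ± 0.07, Birc5 by 0.59 ± 0.08 and Hmmr by 0.55 ± 0.07. Camera gave an adjusted p = 2.8e-19 and, with an estimated correlation, an adjusted p = 0.71. S phase genes did not rise with them: of 40 tested, 1 was higher and 4 lower (1 and 6 adjusted over the list alone, 1 and 8 with the sample division as a term), with a median of -0.06 (-0.17 and 0.02 in the same order of samples, camera adjusted p = 0.11). Casp8ap2 (-0.31 ± 0.07), Slbp (-0.26 ± 0.06) and Ung (-0.43 ± 0.11) were lower and E2f8 was higher (0.30 ± 0.08). The call of Ung ended without control replicate 2 or 4 (adjusted p up to 0.066), and that of E2f8 (up to 0.078) held only without control replicate 4, ASO replicate 1 or ASO replicate 2. Camera called the S phase list lower without ASO replicate 3 (adjusted p = 0.024) or ASO replicate 4 (0.0050), and in samples 1 and 2 alone (1.7e-04). With an estimated correlation over all 8 libraries its adjusted p = 0.80, and 16 of 35 divisions of the libraries gave a camera p as small. Of 6 tested replication-dependent histone genes 1 was higher and 1 lower (2 and 2 adjusted over the list alone, camera adjusted p = 0.58).

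**Figure D2:**
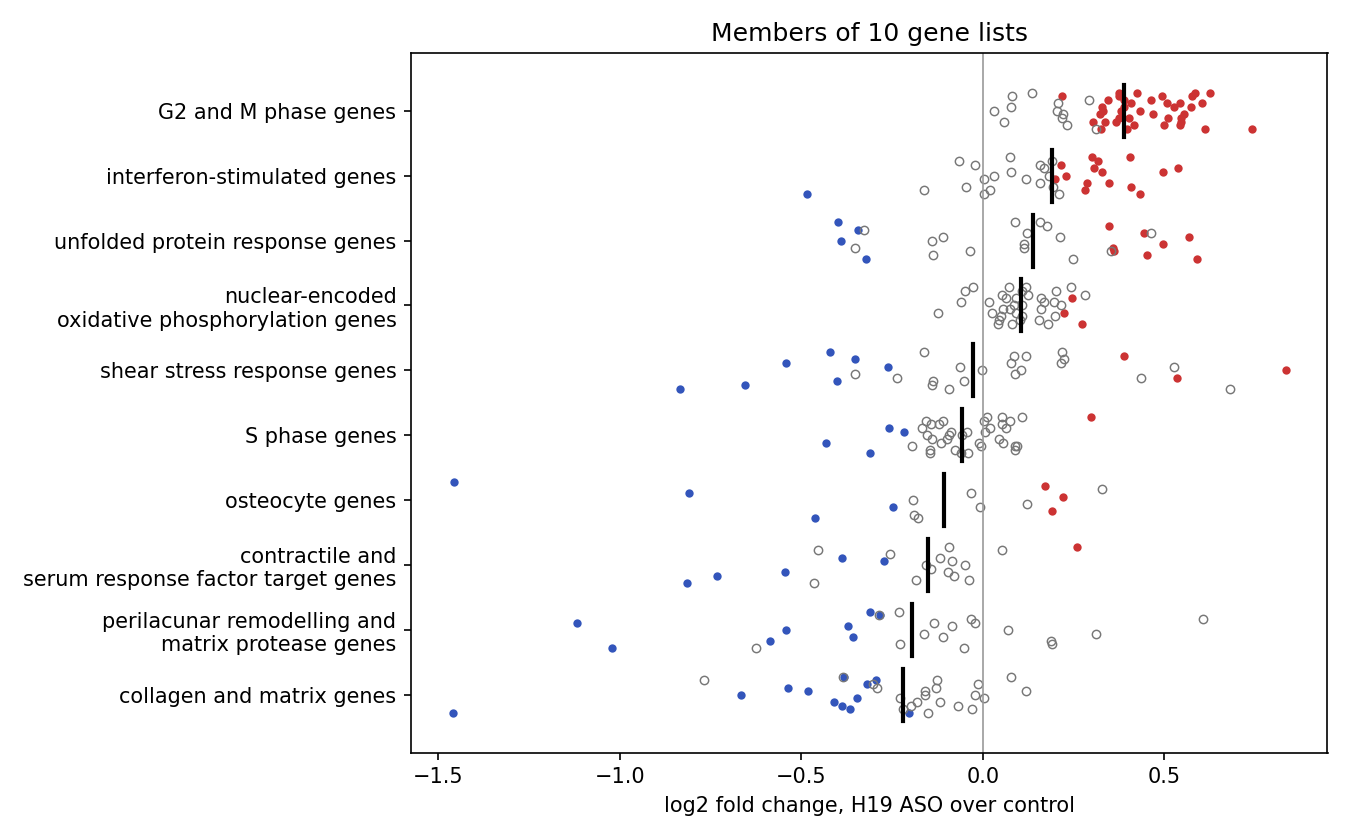
Log2 fold change (H19 ASO over control) of each tested member of 10 gene lists, ordered by median. Filled points passed an adjusted p of 0.05 (red higher, blue lower), open points did not, and black bars are medians, highest for G2 and M phase genes (0.39) and lowest for collagen and matrix genes (-0.22).

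Of 34 tested interferon-stimulated genes, 15 were higher and 1 lower (18 and 2 adjusted over the list alone), with a median of 0.19 (0.20 in samples 1 and 2, 0.18 in samples 3 and 4). Lgals3bp, a secreted glycoprotein gene, rose from 1344 ± 93.2 CPM to 1814 ± 115 CPM (log2 fold change 0.43 ± 0.07, adjusted p = 0.0013). The RNA-sensing oligoadenylate synthetase genes Oas3 (0.54 ± 0.09) and Oas1a (0.41 ± 0.08) rose, both with counts that were not whole. The synthetase-like gene Oasl1 (0.35 ± 0.07) rose too. Ifi27 was the lower member (-0.48 ± 0.13, named after its value was seen). Camera gave an adjusted p = 5.2e-05 and, with an estimated correlation, an adjusted p = 0.73. Of 29 NF-kappaB and inflammatory genes 5 were higher and 4 lower (5 and 6 adjusted over the list alone, 7 and 7 with the sample division as a term, camera adjusted p = 0.71). Csf3, a granulocyte growth factor gene, rose by 2.13 ± 0.35 from 0.27 ± 0.10 CPM, and Nfkbiz fell by 0.33. Of 20 senescence-associated secretory genes 1 was higher and 3 lower (2 and 5 adjusted over the list alone, also with the sample division as a term, camera adjusted p = 0.48), among them Hgf (-0.41 ± 0.08) and Cdkn1a (-0.21 ± 0.06), whose call held only without control replicate 2, ASO replicate 2 or ASO replicate 4 (adjusted p otherwise up to 0.090).

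Among 28 genes of the unfolded protein response 8 were higher and 4 lower (12 and 5 adjusted over the list alone, 14 and 7 with the sample division as a term, camera adjusted p = 0.11). The higher members included the endoplasmic reticulum chaperones Calr (911 ± 86.4 CPM to 1372 ± 97.0 CPM, log2 fold change 0.59 ± 0.08, adjusted p = 3.6e-04), Pdia4 (0.45 ± 0.07) and Pdia6 (0.36 ± 0.06), whereas the transcription factor gene Xbp1 fell by 0.40. Camera called this list without ASO replicate 1 (adjusted p = 0.013) and in samples 3 and 4 alone (0.015), with an adjusted p = 0.79 for an estimated correlation over all 8 libraries and a camera p as small in 14 of 35 divisions of the libraries. Targets of p53 were higher in 5 and lower in 3 of 27 cases (6 and 3 adjusted over the list alone, camera adjusted p = 0.80, with a median and a mean near 0 that differ in sign), with Gtse1 (0.39 ± 0.07), also on the G2 and M list, and Bax (0.35 ± 0.08) higher and Plk2 (-0.39 ± 0.08) and Sesn1 (-0.39 ± 0.09) lower. Of 24 antioxidant targets of NRF2 2 were higher and 3 lower (5 and 4 adjusted over the list alone, 8 and 5 with the sample division as a term, camera adjusted p = 0.61). Txn1 rose by 0.51 ± 0.10 and Gstm1 (-0.52 ± 0.10), Hmox1 (-0.58 ± 0.14) and Gsta4 (-0.46 ± 0.12) fell. The call of Gsta4 ended without control replicate 4 (adjusted p = 0.064), and Gstm1 had a count that was not whole.

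Nuclear-encoded genes of oxidative phosphorylation were higher in 3 of 38 cases and lower in 0, also adjusted over the list alone, and in 12 and 0 with the sample division as a term, with a median of 0.11 (0.07 in samples 1 and 2, 0.16 in samples 3 and 4). The 3 were Uqcrc1 (0.27 ± 0.05), Ndufa4 (0.25 ± 0.06) and Atp5b (0.22 ± 0.06). Camera gave an adjusted p = 0.0026, an adjusted p = 0.73 with an estimated correlation, and an adjusted p = 0.19 in samples 1 and 2 alone. The call of Ndufa4 ended without control replicate 2, ASO replicate 3 or ASO replicate 4 (adjusted p up to 0.069), and that of Atp5b (up to 0.075) held only without control replicate 3, ASO replicate 1 or ASO replicate 2. Mitochondrially encoded genes are not analysed here. Of 32 glycolysis and hypoxia genes 3 were higher and 3 lower (9 and 3 adjusted over the list alone, 9 and 4 with the sample division as a term, camera adjusted p = 0.76, with a median and a mean near 0 that differ in sign). Car9, a carbonic anhydrase gene induced by hypoxia, fell from 288 ± 33.0 CPM to 149 ± 39.8 CPM (log2 fold change -0.95 ± 0.15, adjusted p = 0.0013) and Adm by 0.52, and Ddit4 rose by 0.38 ± 0.09. Of 25 cholesterol biosynthesis genes 1 was higher, Ebp (0.27 ± 0.08, named after its value was seen), and 0 passed adjusted over the list alone (1 higher and 1 lower with the sample division as a term, camera adjusted p = 0.76).

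Of 30 tested markers of other cell types 11 passed (36.7%), in both directions, against 14.6% of all tested genes. Of 6 chondrocyte markers 0 were higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.11): Col10a1 (-0.93 ± 0.17, adjusted p = 0.0039), Col2a1 (-1.07 ± 0.24, adjusted p = 0.0093) and Sox9 (-0.44 ± 0.11, adjusted p = 0.017), the last lost without control replicate 4 (adjusted p = 0.054). Of 6 macrophage and monocyte markers 1 was higher and 1 lower (2 and 1 adjusted over the list alone, camera adjusted p = 0.48), of 6 osteoclast markers 0 and 1 (1 and 2, and 0 and 3 with the sample division as a term, camera adjusted p = 0.21). Lists with fewer than 5 tested members had no set test. They gave 1 higher and 0 lower of 3 endothelial, 0 and 1 of 4 adipocyte, 0 and 2 of 3 skeletal muscle and 1 and 0 of 2 epithelial markers (adjusted over the list alone 1 and 0, 0 and 2, 0 and 2, and 1 and 0, the same with the sample division as a term). Of these, named after their values were seen, the macrophage marker Cd68 had a log2 fold change of 1.54 ± 0.13 and Cd74 -0.52 ± 0.11, Ocstamp -1.02 ± 0.27, Esam 1.48 ± 0.39, Cebpa -0.46 ± 0.09, Acta1 -1.13 ± 0.21, Des -0.55 ± 0.13 and Elf3 2.11 ± 0.36. Some of these lists held genes of low expression. The epithelial median was 1.12 (2 members), but 0.066 with TPM + 1 (1 member). The endothelial median went from 0.13 (3 members) to 0.0080 with FPKM + 1 (2 members). Skeletal muscle (-0.33, 3 members) and adipocyte medians (-0.22, 4 members) kept their sign with FPKM + 1.

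In all, 6 of the 29 tested lists passed camera with its preset correlation, 3 higher and 3 lower, and 0 passed with an estimated correlation, where 0.71 was the lowest adjusted p and 1 list had an unadjusted p under 0.05. With fry, which tests whether the genes of a list shift in a direction on average and not whether they differ from other genes, 8 lists passed. They were G2 and M genes (higher), collagen and matrix genes and perilacunar genes (lower), and the osteocyte (adjusted p = 0.034), shear stress (0.032), imprinted (0.020), osteoclast marker (0.032) and chondrocyte marker (0.020) lists, all 5 lower. Members of these 5 lists did not all fall. Log2 fold changes were positive and negative in 5 and 9 osteocyte, 14 and 16 shear stress and 2 and 6 imprinted genes. They were so in 1 and 5 osteoclast and 3 and 3 chondrocyte markers. Other divisions of the same 8 libraries into 4 and 4 often gave as many lists: 16 of 35 did, the real division included. In the other divisions between 0 and 33 single genes passed. Each of them mixes ASO and control libraries, which puts the difference between the groups in the residual spread and lowers the count.

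**Figure D3:**
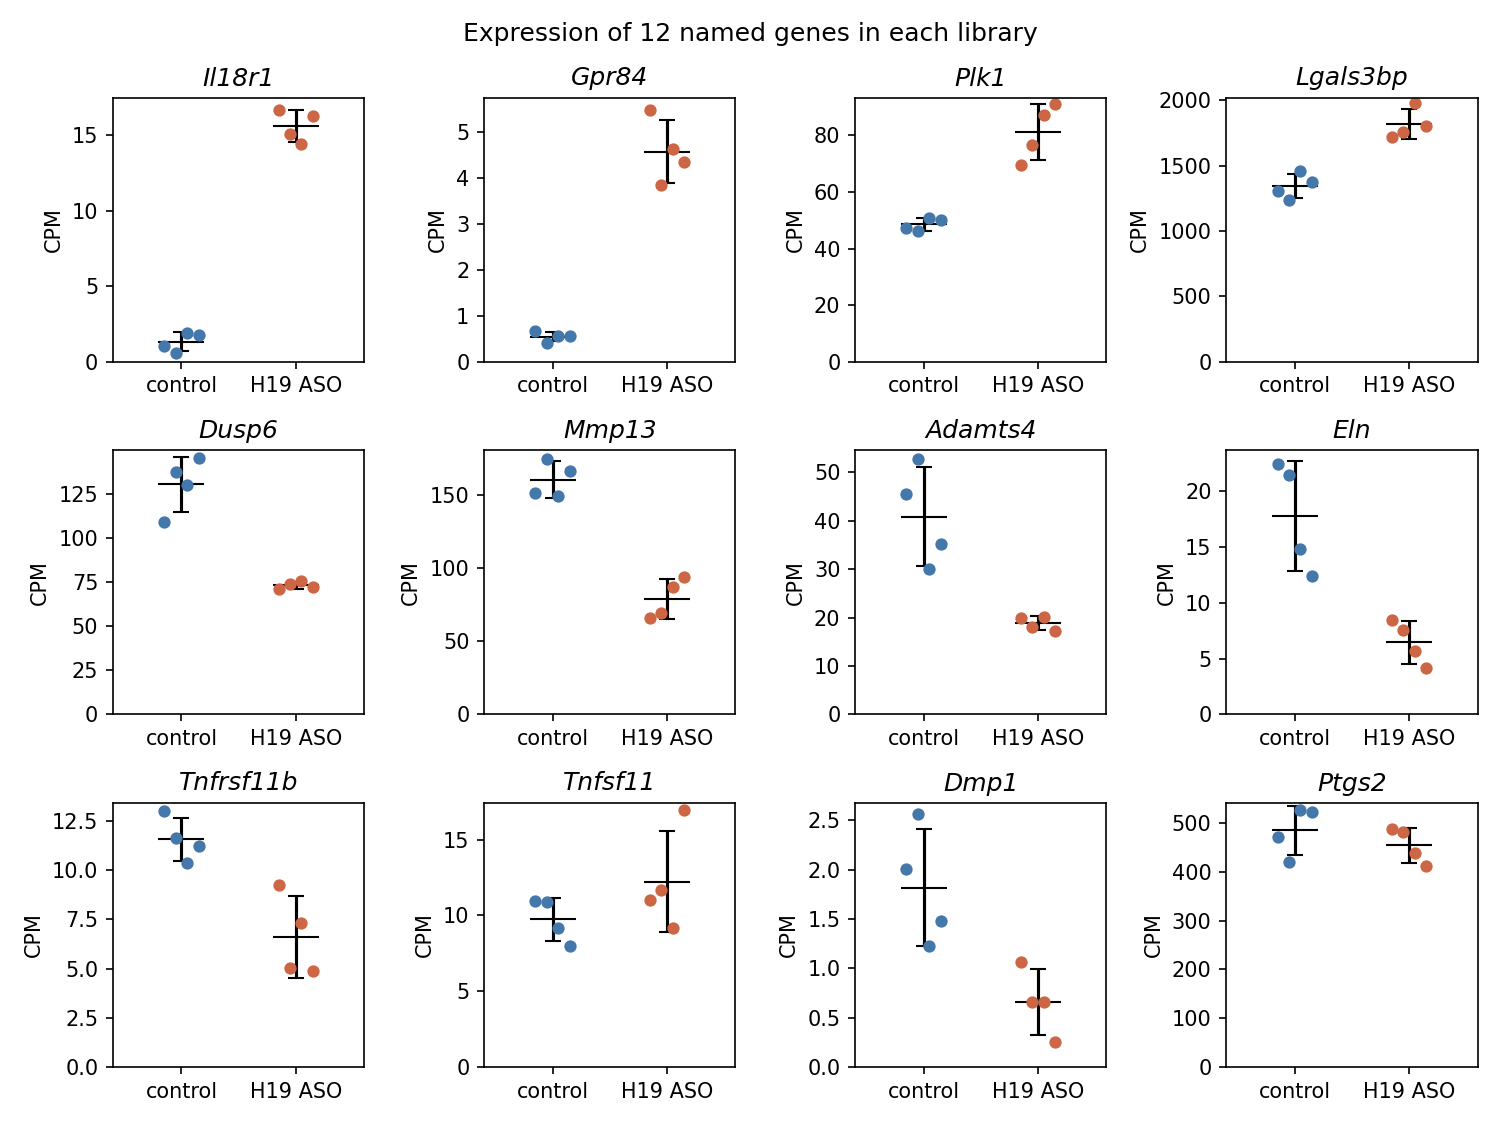
CPM of 12 named genes in each library (points), with the mean and SD of each group of 4 (bar and whiskers) on axes that start at 0. Il18r1 lies at 1.34 CPM in control and 15.6 CPM in H19 ASO libraries, Mmp13 at 161 and 79.1 CPM, and Tnfsf11 and Ptgs2 did not pass the test.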

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

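The split test of the single gene lists was chosen after the split result for their number had been seen. In 12 of 282 groups of 4 libraries, 1 library lay far from the rest, where chance, at 1 in 20, gives about 14.1. Among named genes, Il4i1 was at 0.41 CPM in control replicate 3 against at most 0.051 in the other controls. Cyp2f2 was at 0.50 CPM in ASO replicate 4 and Sox9 at 160 CPM in the same library, both below the other ASO libraries. In ASO replicate 2, Cnnm1 (0.56 CPM), Tagln2 (328 CPM) and Cdc25a (34.3 CPM) were low and Pgam1 (767 CPM) was high. Fzd1 was high in ASO replicate 1 (24.7 CPM). Of the list means in log2 CPM, the Wnt targets and antagonists were high in ASO replicate 1 (5.50), cholesterol biosynthesis was low in ASO replicate 2 (6.10), replication-dependent histones were low in ASO replicate 3 (2.06) and chondrocyte markers were low in ASO replicate 4 (4.48).

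The 35 divisions of the 8 libraries into 4 and 4 separate the results into 2 kinds. The real division was the only 1 of the 35 to reach its 1790 genes, 869 higher, 921 lower and 224 with at least 2-fold change. These counts overlap, and 1 of 35 is the smallest share possible. Every other division mixes ASO and control libraries, which puts the difference between the groups in the residual spread and lowers its count. Chance differences between cultures are not covered, as the libraries of a group may be technical repeats. The highest other values were 33 genes, 20 in a direction and 4 with at least 2-fold change, all in the division that set samples 1 and 2 against samples 3 and 4. That fit leaves the difference between the groups in the residual spread: with group as a term the same division gave 1443 genes, 642 higher and 801 lower in samples 3 and 4. In the like fit, with the division as a term, ASO against control gave 3136 genes. The division is balanced between the groups. All other divisions gave 0 genes in edgeR. For the count of gene lists chance cannot be excluded: 16 of 35 splits gave at least 6 lists, and up to 10. List by list, a camera p as small came from 1 split, the real one, for perilacunar remodelling and matrix protease genes (8.6e-04, lowest other 0.0018). It came from 2 splits for G2 and M phase genes (lowest other 3.3e-25), 4 for collagen and matrix genes (1.2e-09), 5 for interferon-stimulated genes (5.4e-10), 11 for contractile and serum response factor targets (2.7e-07) and 12 for oxidative phosphorylation (3.6e-11).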

How the results depend on the processing

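No called named gene or list reversed under any setting. Across settings, other called genes were compared for sign where both fits called them, and these kept it. The balance of calls did turn, from 48.5% higher to 52.3% with upper-quartile scaling, 54.8% with library size and 54.2% with FPKM + 1, and was 42.2% with TPM + 1. List medians near 0 also changed sign, such as that of p53 targets with DESeq2 size factors (-0.00036). Medians further from 0 did so with FPKM + 1, where fewer members were tested. That of macrophage and monocyte markers went from 0.36 (6 members) to -0.023 (4 members). That of osteocyte genes went from -0.11 (14 members) to 0.0035 (13 members). H19 is not analysed here, so its log2 fold change has no value. The 1790 genes became 1773 with DESeq2 size factors, 1765 with limma-voom and 1981 with DESeq2, which has no set test here. Leaving out each library gave 1105 to 1940 genes past the threshold, H19 ASO against control, with 538 to 965 as genes higher with H19 ASO and 567 to 975 as genes lower with H19 ASO. It gave 206 to 243 genes past the threshold with at least 2-fold change, 6 to 7 gene lists past the threshold and, for the principal components, 45.3% to 49.8% of variance on the first. Fewer libraries entered these fits. Of 100 called named genes 80 kept their call in all 8 of these fits. An adjusted p under 0.01 left 702 genes, 346 higher and 356 lower. The count with at least 2-fold change, 224 as reported, was 35 with the stricter filter, which removes low genes. On log2 scales that understate low genes it was 22 (FPKM + 1), 90 (FPKM + 0.1), 20 (FPKM, no filter), 46 (TPM + 1), 135 (TPM + 0.1) and 42 (TPM, no filter). Unfiltered FPKM gave 532 lower genes, and unfiltered TPM gave 1167 genes, 554 higher and 613 lower; the cause was not tested. The first component held 33.8% without a filter, 50.6% with the stricter one, 47.8% for FPKM + 1, 43.4% for TPM + 0.1 and 42.6% for unfiltered TPM. With an estimated correlation camera called 0 lists (1 at an unadjusted p under 0.05), whereas fry called 8, of which 3 were among the 6.

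The following settings were chosen after the data were seen; counts are genes past the threshold, H19 ASO against control, split into genes higher with H19 ASO and genes lower with H19 ASO, and the variance is from the principal components. With samples 1 and 2 against 3 and 4 as a term, 3136 genes passed, 1560 higher and 1576 lower, including all 1790. All 100 called named genes kept their call, and Tnf, Cox6c and Piezo1 gained one (adjusted p = 0.0038, 0.0084 and 0.033). Samples 1 and 2 alone gave 1022 genes, 495 higher and 527 lower, with 64.5% of variance on the first component, and samples 3 and 4 alone gave 65.6%. Fewer libraries enter these last fits.

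The replicate number as a block gave 2575 genes past the threshold, H19 ASO against control, with 1267 genes higher with H19 ASO and 1308 genes lower with H19 ASO, and kept all 6 lists. The numbers are not shown to pair the samples: deviations of same-numbered libraries correlated at 0.049 to 0.21, and 2 of 8 libraries correlated best with their own number. Depth limits mainly the genes near 1 CPM, about 19.5 reads.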

Other observations

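The gene lists in this part, and the tests of sample division for G2 and M genes, of the phase mix and of the clock genes by sample division and harvest, were chosen after the data were seen. Genes that control mineral formation were lower in 8 of 13 cases and higher in 1. Of the called members, Dmp1, Bglap2, Bglap and Alpl were also counted in the osteocyte or osteoblast lists. Members act for and against mineral formation, so the count gives no net direction for it. Enpp1, which makes the mineralisation inhibitor pyrophosphate, fell from 179 ± 11.3 CPM to 103 ± 16.2 CPM (SD, n = 4, log2 fold change -0.80 ± 0.09 SE, edgeR adjusted p = 1.9e-04). Ank, which exports it, fell from 528 ± 69.3 CPM to 294 ± 59.0 CPM, and the phosphate transporter gene Slc20a1 and Phospho1 fell by 0.70 and 0.58, while Alpl, which breaks pyrophosphate down, rose by 0.37. Small leucine-rich proteoglycan genes were lower in 5 of 10 cases and higher in 0, led by Ogn (229 ± 21.3 CPM to 117 ± 10.1 CPM, adjusted p = 1.7e-05) and Omd (-1.27 ± 0.18). Basement membrane genes were lower in 9 of 17 cases and higher in 0, with the laminin gene Lama5 at -0.89 ± 0.09. Of the lower proteoglycan and basement membrane genes, Dcn, Col4a1 and Col4a2 were also on the collagen and matrix list. Antigen processing and class I genes were higher in 6 of 19 cases and lower in 0, among them Tapbp (0.41 ± 0.06) and Calr, which was also on the unfolded protein response list. The class I genes themselves did not pass: H2-D1 (-0.15 ± 0.07), B2m (-0.12 ± 0.07), H2-T23 (-0.04 ± 0.07), H2-K1 (-0.03 ± 0.08) and H2-M3 (0.02 ± 0.09). Camera gave adjusted p = 3.2e-04, 5.8e-05, 8.2e-06 and 0.0020 for these 4 lists, and 0.081, 0.081, 0.14 and 0.28 with an estimated correlation. A camera p as small came from 1, 1, 1 and 6 of the 35 splits, in the same order. As these lists were chosen after the values of the real division were seen, neither the p-values nor the splits are independent support.

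Circadian clock genes moved in opposite directions. Of 10 genes driven by E-boxes or D-boxes 6 were higher and 0 lower, with Dbp at 1.18 ± 0.11 (25.1 ± 1.85 CPM to 57.1 ± 10.5 CPM, adjusted p = 4.5e-05) and Nr1d1 at 0.78 ± 0.17. Of 6 genes driven by ROR elements 5 were lower and 0 higher, with Arntl at -1.34 ± 0.13 (34.6 ± 4.82 CPM to 13.7 ± 2.71 CPM, adjusted p = 6.0e-05) and Cry1 at -0.51 ± 0.09. The difference between the medians of the 2 lists was 1.01, and it was 0.80 in the part of the samples where it was smaller. Scaling bears on it little by construction, since a factor moves all genes alike, and the lowest value, 0.91, came on a scale with an added pseudocount. Camera gave an adjusted p = 5.8e-05 for each list, and 0.081 and 0.11 with an estimated correlation, and 2 and 1 of the 35 splits gave a p as small. Both clock lists were chosen after the data were seen, so these tests are no independent support. A candidate explanation is that the groups were at another phase of the clock when harvested. Harvest times are not in the labels, so this cannot be told apart from an effect of the ASO on the clock, which stays open and untested.

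The rise of G2 and M phase genes was present in both parts of the samples, with a median of 0.33 in the lower. The lowest median over the scalings was 0.35. These scalings left the median of all tested genes between -0.015 and 0.020. They could hardly have removed the rise, so this test does not decide its source. More cycling cells with the same mix of phases would raise S phase genes as well. The mean of G2 and M genes minus that of S phase genes was 0.44 higher in ASO libraries (log2 CPM, SD 0.088 in control and 0.096 in ASO, exact two-sided permutation p = 0.029, the smallest that 4 against 4 can give). The mean of G2 and M genes alone gave the same p. As this test of the phase mix was chosen after the data were seen, its p is no independent support. The S phase mean alone differed by -0.061 (SD 0.018 in control and 0.10 in ASO, exact permutation p = 0.37). The S phase median was -0.06 (-0.17 in samples 1 and 2, 0.02 in samples 3 and 4), with 1 gene higher and 8 lower with the sample division as a term. A larger share of cells in G2 or mitosis, from less H19, culture density or harvest time, may be involved and was not tested. As another division of the libraries gave this list a smaller camera p, the set test is not relied on. The pattern is described by its 40 called genes, which vary together (estimated correlation 0.69, with group as the single term) and are not 40 independent results.

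Large rises lay mostly in genes of low expression: 140 of the 157 genes that rose at least 2-fold were below 4 CPM on average, as were 45 of the 67 that fell as much. Background reads, such as from genomic DNA, would raise low genes as a class, but the median log2 fold change of 1861 tested genes below 4 CPM was -0.0099, although reads in genes below the filter were 397 ± 3.69 per 1000000 in control and 426 ± 23.6 in ASO libraries (SD). Reads shared between copies, if counts that are not whole mark them, are not the main source, since 7.14% of the rising genes had counts that were not whole, against 18.1% of other genes below 4 CPM. Another gene that rose at least 2-fold, of any expression, lay within 100 kb of 15.7% of them, such as Hsf5 beside Rnf43, too few to explain the whole pattern but as high as the highest of 1000 random sets matched on expression (median 5.71%). Il1rl2 and Il18r1 were another such pair, near the 100 kb limit: on chromosome 1 Il1rl2 ended at 40367555 and Il18r1 began at 40465552. Overlapping transcripts or regional changes may account for the share with a neighbour, though the annotated positions of Il1rl2 and Il18r1 do not overlap. An effect of the oligonucleotide apart from H19 stays open, since what the control cells received is not stated and there is no further treated group.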
